A study of Homo sapiens with 4 samples.

How the data were processed

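The series holds 4 GRO-seq libraries of human CD34+ derived erythroblasts, 2 with vehicle and 2 with 1 µM GC-1 for 6 h from day 14. Per the labels' protocols, nuclei ran on with bromouridine, labelled RNA was pulled down, tailed with poly(A), reverse transcribed, circularised, relinearised and amplified by PCR, with no molecular identifiers named. Per the submitters' processing notes, Bowtie2 2.2.6, SAMtools, HOMER 4.8.2 and edgeR were used with the build hg19.

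A table of the whole series holds 26457 entries with 26456 symbols. Per the file headers, HOMER counted reads on a gene's own strand over the whole gene, kept at most 3 reads per position and condensed each gene to 1 transcript. Its 4 library columns were deposited as a signal: the authors' read counts times 1 factor per library, so that the columns have equal totals. The authors' log2 fold change of GC-1 over vehicle and the authors' p-value and adjusted p-value stand beside them in the deposited table, made with the run as a batch per the file headers. A further table per run was deposited by the authors in FPKM, scaled by gene length and mapped reads, and each table gives the gene's length in bases. The FPKM tables share 19890 (run 66) and 19877 (run 80) transcripts with the series table. Whole-gene counts do not separate paused polymerase near the start from the gene body.

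Every nonzero value of the series table was a whole multiple of 1 step per library within a tolerance of 0.02 (100% of values), so reads were recovered as whole numbers. Total mapped reads followed from the ratio of reads to FPKM: 5066557 and 4521586 for vehicle and 2385529 and 3251525 for GC-1 in runs 66 and 80. These reads are counts recovered from deposited scaled values. The recovered reads were turned into RPKM with the gene reads of each library as the total. XIST, TSIX and genes on chromosome Y (118 genes) were left out, and 26338 genes stayed.

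The design fixed before the data were examined tests log2(RPKM + 0.1) with limma 3.58.1 (trended eBayes, R 4.3.3), the run as a block and genes at an RPKM of at least 0.5 in at least 2 libraries, two-sided, with Benjamini-Hochberg adjustment at 0.05. Differences on this scale understate the change of low genes. The block is the sequencing run that the labels name, so it pairs the libraries. Run differences of the vehicle and GC-1 libraries correlated across genes with a Pearson r of 0.08 (0.15 for NM transcripts of at least 1000 bases). With the block 1 residual degree of freedom is left and the prior adds 1.81. Because the reads were recoverable, edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, run as block) was run on them, and DESeq2 1.42.0 beside it. The design had foreseen plain counts or plain RPKM values, and the deposited unit was neither.

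On simulated data for the GC-1 and vehicle comparison, with the real means and depths and 1 common dispersion for all genes (a biological coefficient of variation of 0.062), edgeR recovered 52.2% of 1.5-fold, 73.4% of 2-fold and 98.4% of 4-fold changes among 14172 genes tested and called 11 unchanged genes. In the same simulation limma with the block recovered 2.17% of 4-fold changes among 10978 genes tested, 0% of smaller ones, and called 42 unchanged genes. DESeq2 recovered 78.8% of 4-fold changes and called 0 unchanged genes. With no block limma recovered 73.9% of 4-fold changes and called 62 unchanged genes. The simulation held no run effect and drew counts from a model of edgeR's kind with edgeR's own dispersion. It could therefore not show how many of edgeR's calls on the real libraries are right. Since limma with the block and 1 residual degree of freedom recovered few changes, edgeR's test is the one by which genes are described. That choice was made after the data had been seen, and limma's count stands beside it.

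The 29 gene lists, with 572 genes, were fixed with the design and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, for lists of at least 5 tested genes. A further 7 lists were written after the data had been seen: luminal breast epithelium, long neuronal genes, prostate epithelium, neurons, hepatocytes, fibroblasts and endothelium. In edgeR's test the last 5 had 3 of 5, 6 of 8, 0 of 1, 1 of 3 and 1 of 3 members higher, and 0, 0, 0, 0 and 1 lower. The 95th percentile of the rise of the luminal and long neuronal genes (54 genes) set the log2 bound of 1.89 for edgeR's glmTreat. Random lists drew each member from the 200 genes nearest in mean read density.

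Genes are named by a rule fixed with the design: the 12 largest changes in each direction past an adjusted p of 0.05 with the same direction in both runs, or by the smaller change of both runs at a mean RPKM of at least 1 where fewer than 5 pass, members of the thyroid hormone response and coregulator lists past an unadjusted p of 0.05, THRA, THRB, NCOA4 and KLF9 in any case, and up to 4 members of each other list with the smallest p. The same rule was applied to the edgeR test. Some single genes that the rule names are not reported. ITFG1, GREB1 and RNA45S5 were chosen after their values were seen. Alternatives covered the block, scaling, filters, pseudocounts of 0.01 and 1, transcript class, test and each library left out. Intervals and floors (3 reads) cover counting error only. Coordinates are those of the deposited hg19 tables, written 1-based. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.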

Results

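Nascent transcription was measured by GRO-seq in erythroblasts, the nucleated precursors of red cells, grown from primary human CD34+ progenitors. In GRO-seq, engaged RNA polymerases extend their transcripts in isolated nuclei with bromouridine and the labelled RNA is sequenced, so reads on a gene reflect polymerases on it and not stored RNA. At day 14 the cells were given 1 µM GC-1 or vehicle for 6 h. GC-1, or sobetirome, is a synthetic thyroid hormone analog that binds thyroid hormone receptors. There were 4 libraries, 2 per condition, and each of sequencing runs 66 and 80 held 1 vehicle library and 1 GC-1 library (replicates 1 and 2). The titles of 2 samples name T4, whereas their other labels name GC-1, which is followed here. Nothing in the labels says that the replicates came from separate cultures or donors, so p-values measure only the spread between these libraries.

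The GC-1 libraries were the shallower ones. The vehicle libraries held 4048018 (run 66) and 3387345 (run 80) reads in genes, and the GC-1 libraries 1655047 and 1946045. Of all mapped reads, 79.9% and 74.9% were counted on a gene's own strand with vehicle, against 69.4% and 59.9% with GC-1. The ribosomal RNA gene RNA45S5 took 1.84% and 2.06% of gene reads with vehicle and 3.70% and 3.22% with GC-1. At most 3 reads per position were kept, which can hold back a densely read gene more in the deeper vehicle libraries. These shares alone therefore do not show a rise of ribosomal RNA transcription. The chi-square of the gene counts per degree of freedom was 2.38 between the vehicle libraries and 3.19 between the GC-1 libraries, against 15.2 and 13.2 between conditions within runs 66 and 80. The pairs between conditions also differed more in depth, on which the limit per position acts. The larger values therefore cannot be credited to GC-1 alone.

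The comparison asked which genes changed their transcription within 6 h of GC-1. The clearest rise was that of NETO2, which encodes an auxiliary subunit of kainate receptors (hg19 chromosome 16, 47115432 to 47177936). Its density went from 0.242 ± 0.0214 RPKM with vehicle to 11.1 ± 0.477 RPKM with GC-1 (SD, n = 2 each), 45.7-fold higher. KLF9, a transcription factor gene known to respond to thyroid hormone (chromosome 9, 72999514 to 73029573), rose 4.10-fold, from 0.639 ± 0.0146 to 2.62 ± 0.247 RPKM. ACSBG1, an acyl-CoA synthetase gene (chromosome 15, 78463188 to 78527049), fell from 4.90 ± 0.0168 to 0.642 ± 0.0426 RPKM, 7.64-fold lower. SLC16A9, a monocarboxylate transporter gene (chromosome 10, 61410523 to 61469649), fell from 3.44 ± 0.153 to 0.501 ± 0.116 RPKM, 6.78-fold lower.

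By edgeR's quasi-likelihood test on reads, 5411 of 14135 genes changed at an adjusted p under 0.05, 3080 higher and 2331 lower with GC-1. Rose and fell are used here of genes past this test, and folds are edgeR's. The limma test on log2 RPKM with the run as a block called 0 of 11026 genes, with 3005 at an unadjusted p under 0.05 and a smallest adjusted p of 0.058, and DESeq2 called 1804. The count of 5411 depended on single libraries: it was 1398 without vehicle replicate 1, 2930 without vehicle replicate 2 and 3233 without GC-1 replicate 2, where 127 of the 5411 genes changed sign. Without the run block edgeR called 3350 genes and limma 431. Fits with a library left out, here and below, had no run block, since it would leave no residual degree of freedom. Their values therefore mix the loss of the block with the loss of a library, and edgeR's 3350 is the count to set beside theirs. The zero point depended on the scaling: the median log2 change of all genes was -0.09 relative to gene reads and -0.33 relative to mapped reads, and with mapped reads edgeR called 1977 genes higher and 4353 lower. Medians of lists are therefore those of limma's log2 differences relative to the median of all genes, unless named as edgeR's. Camera was run on log2 RPKM and, chosen after the data had been seen, on the reads, where the smallest adjusted p with an estimated correlation was 0.703 among the 29 lists fixed with the design.

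**Figure D1:**
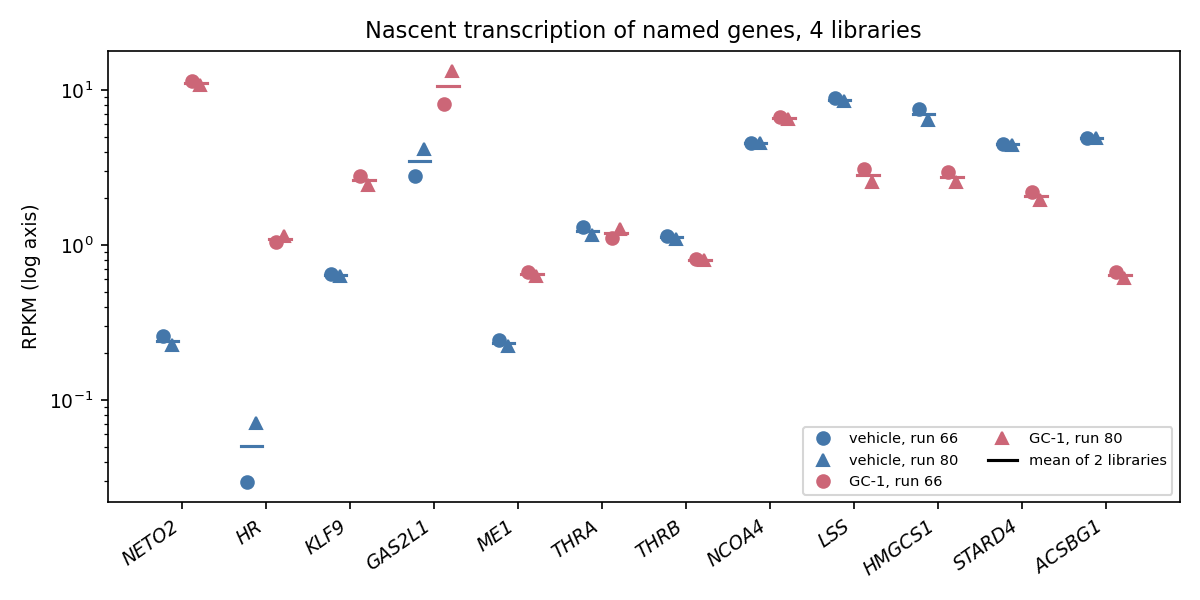
RPKM per library (log axis) of 12 named genes: blue marks are vehicle and red marks GC-1, circles run 66 and triangles run 80, and bars the mean of 2 libraries. NETO2 lies at 0.257 and 0.227 RPKM with vehicle and at 11.4 and 10.8 RPKM with GC-1, and LSS, HMGCS1, STARD4 and ACSBG1 are lower with GC-1 in both runs.

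Some genes that mark other cells also rose with GC-1, as did 3080 of all 14135 genes tested. Of 9 mast cell, basophil and eosinophil markers 4 rose and 0 fell, of 10 megakaryocyte markers 3 and 0, of 5 neutrophil precursor markers 3 and 1, and of 5 macrophage markers 1 and 0, and the 1 lymphocyte marker tested was not called (4 and 0, 3 and 0, 4 and 1, 1 and 0, and 0 adjusted over the list alone). EPX, eosinophil peroxidase, rose 2.65-fold and MPO, myeloperoxidase, 2.14-fold. The first 3 of these lists passed camera on log2 RPKM (adjusted p = 0.00368, 0.0399 and 0.00454, each adjusted p = 0.574 with an estimated correlation) and did not pass on the reads (adjusted p = 0.137, 0.448 and 0.327). The megakaryocyte list also lost its camera call with no replicate block (adjusted p = 0.0617), no filter on low values (0.178), median centring (0.0561) or limma without trend (0.0584). It lost the call too without vehicle replicate 1, GC-1 replicate 1 or vehicle replicate 2. It kept the call with the other scalings and pseudocounts, on the deposited FPKM tables and for NM transcripts. In lists written after the data had been seen, 22 of 28 genes of luminal breast epithelium rose and 1 fell, with a median 1.32 above that of all genes. Of 26 long neuronal genes 25 rose and 0 fell, with an edgeR median log2 change of 1.31, where the edgeR median of all genes was 0.03. GREB1, an estrogen-induced gene of breast epithelium, had 457 and 462 reads with vehicle and 527 and 596 with GC-1. The lowest decile of read density had median log2 changes of 0.78 in run 66 and 1.05 in run 80. Against a log2 change of 1.89, the 95th percentile of the luminal and long neuronal genes, edgeR's glmTreat called 6 genes: NETO2, HR, LMOD1 and FGF17 higher, ACSBG1 and SLC16A9 lower. KLF9 was not among them.

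**Figure D2:**
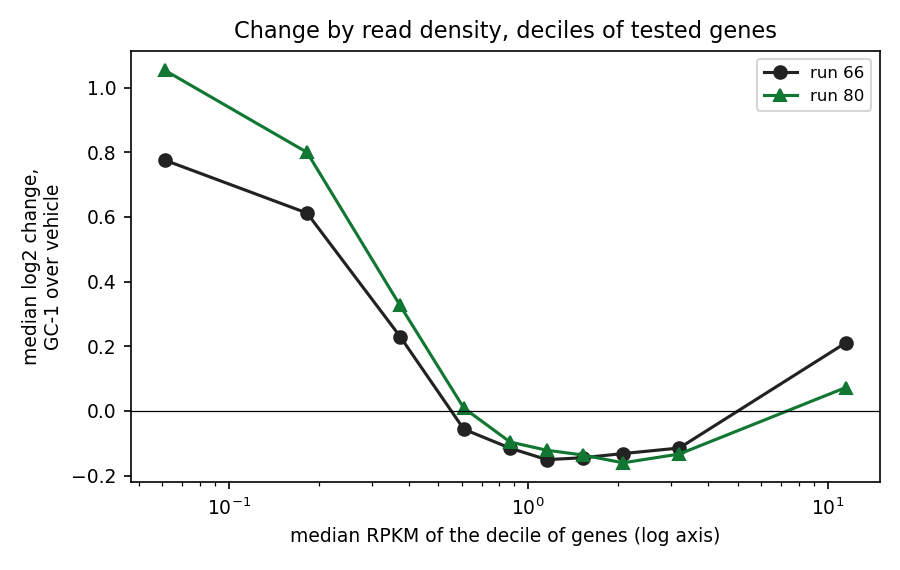
Median log2 change, GC-1 over vehicle, of the tested genes in deciles of mean read density (y axis) against the median RPKM of each decile (log x axis), with circles for run 66 and triangles for run 80. The decile at 0.061 RPKM lies at 0.78 and 1.05, the decile at 2.07 RPKM at -0.13 and -0.16.

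Among known thyroid hormone response genes, 8 of 16 rose and 3 fell (9 and 3 adjusted over the list alone, and 6 called by limma adjusted over the list alone). HR, a corepressor of nuclear receptors (chromosome 8, 21971933 to 21988565), had 2 and 4 reads with vehicle and 29 and 37 with GC-1, a ratio of 22.7 in pooled reads (95% counting interval 9.90 to 64.1). GAS2L1, a cytoskeletal linker gene, rose 3.06-fold, PPARGC1A, a coactivator of mitochondrial genes, 3.64-fold and ME1, cytosolic malic enzyme, 2.78-fold. TMEM140, FURIN and KLF13 rose 2.44-fold, 1.34-fold and 1.32-fold. CA2, a carbonic anhydrase gene, fell by 0.44 and STAT5A by 0.69 on the log2 scale. The list's median was 0.40 above that of all genes, beside 1.32 for the luminal breast genes, a list written after the data had been seen. The thyroid hormone response list's own median was 0.31 relative to gene reads and 0.05 relative to mapped reads. Of its members HR passed glmTreat. Camera's adjusted p was 0.0228 on log2 RPKM (adjusted p = 0.574 with an estimated correlation) and 0.0211 on the reads, but 0.102 with no filter on low values and 0.087 at a mean RPKM of at least 2. The median lay at the 98.9th percentile of random lists of matched read density in run 66 and the 99.2nd in run 80. Without vehicle replicate 1 edgeR's adjusted p was 0.0755 for TMEM140, 0.419 for FURIN, 0.115 for KLF13, 0.231 for CA2 and 0.0791 for STAT5A. Without vehicle replicate 2 it was 0.171 for FURIN, 0.0506 for KLF13 and 0.120 for STAT5A, and FURIN also lost its call without GC-1 replicate 1 (0.150) or 2 (0.0793), while mapped-read scaling gave 0.460 for FURIN and 0.344 for KLF13. DESeq2 called none of these 5 genes (adjusted p = 0.0549 for TMEM140, 0.459 for FURIN, 0.0717 for KLF13, 0.0529 for CA2 and 0.144 for STAT5A).

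The receptor genes moved little. THRB, counted above among the response genes that fell, went from 1.12 ± 0.0377 to 0.806 ± 0.00993 RPKM, 1.39-fold lower (edgeR adjusted p = 2.06e-09, and 0.0675 without vehicle replicate 1). THRA stood at 1.24 ± 0.0957 RPKM with vehicle and 1.19 ± 0.117 RPKM with GC-1 (edgeR adjusted p = 0.871), lower in run 66 and higher in run 80. Of 18 nuclear receptor coregulators and partners 4 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.233 on log2 RPKM and 0.757 on the reads). NCOA4, a coactivator that also carries ferritin to autophagy, rose 1.45-fold, from 4.55 ± 0.0215 to 6.58 ± 0.124 RPKM, and NCOA3 rose 1.72-fold. NCOR1, the corepressor of unliganded thyroid hormone receptors, fell by 0.39 on the log2 scale. NCOA4 did not pass with mapped-read scaling (edgeR adjusted p = 0.0826) or in DESeq2 (0.0909), nor NCOR1 without vehicle replicate 1 (0.243) or GC-1 replicate 2 (0.0525).

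Genes of cholesterol synthesis were lower with GC-1. Of 20, 13 fell and 0 rose (16 and 0 adjusted over the list alone, and 10 called by limma adjusted over the list alone), and 18 of the 19 in the limma fit were lower in both runs. LSS, lanosterol synthase, fell 3.08-fold, from 8.65 ± 0.298 to 2.81 ± 0.380 RPKM. HMGCS1, an early enzyme of the pathway, fell from 6.97 ± 0.797 to 2.76 ± 0.30 RPKM. STARD4, a sterol carrier, was 2.16-fold lower and INSIG1, a sterol-sensing regulator of the pathway, 1.77-fold lower. The list's median was -0.60 relative to all genes (camera adjusted p = 1.07e-05, and 5.34e-09 on the reads, adjusted p = 0.574 with an estimated correlation). In each run its median lay below those of all 10000 random lists of matched read density.

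Of 19 genes of fatty acid synthesis and oxidation 10 fell and 2 rose (11 and 2 adjusted over the list alone). The desaturase genes FADS1 and FADS2 fell 2.36-fold and 2.06-fold, and the elongase gene ELOVL6 2.03-fold. The median was -0.19 relative to all genes (camera adjusted p = 0.0157, and 0.000229 on the reads, adjusted p = 0.574 with an estimated correlation), at the 2.72nd and 3.16th percentiles of matched random lists in runs 66 and 80.

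**Figure D3:**
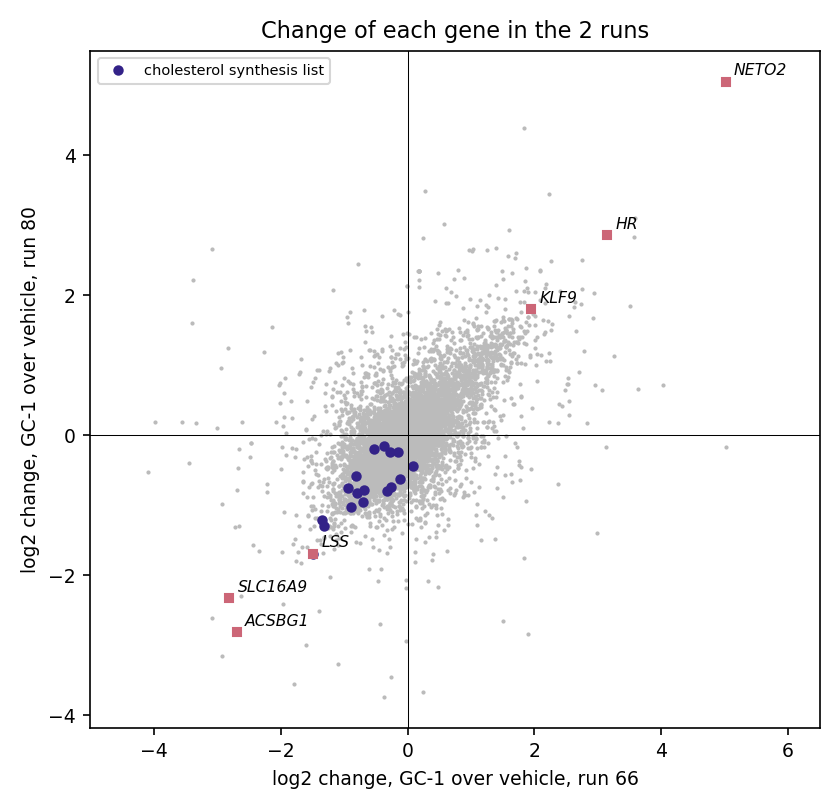
Log2 change of RPKM + 0.1, GC-1 over vehicle, of NM transcripts of at least 1000 bases in run 66 (x axis) against run 80 (y axis), with 1 grey point per gene, the cholesterol synthesis list in violet and 6 named genes as red squares. NETO2 lies at 5.01 and 5.05, and the cholesterol genes lie below 0 in both runs apart from 1 gene in run 66.

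Erythroid genes went both ways. Of 9 genes for globins and their chaperone 5 rose and 0 fell (5 and 0 adjusted over the list alone). HBB, adult beta globin, rose from 430 ± 34.8 to 662 ± 71.5 RPKM, HBD from 86.9 ± 6.90 to 154 ± 14.8 RPKM and HBA1 from 435 ± 49.4 to 722 ± 21.2 RPKM. HBA1 shares near-identical sequence with HBA2, so its reads are uncertain between the copies. The authors counted at most 3 reads per position, and HBB reached 53.0% of that limit with vehicle and 39.5% with GC-1. The globin median was 0.59 above that of all genes (camera adjusted p = 0.00401, and 0.000775 on the reads, adjusted p = 0.574 with an estimated correlation), but at the 48.6th and 68.8th percentiles of random lists of matched read density in runs 66 and 80.

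Of 19 heme synthesis and transport genes 2 rose and 6 fell, and of 17 iron genes 1 rose and 8 fell (3 and 7, and 2 and 8, adjusted over the list alone). The heme exporter gene FLVCR1 fell from 2.31 ± 0.144 to 0.952 ± 0.109 RPKM, and the iron sensor gene TFR2 fell by 0.59 on the log2 scale. Of 29 red cell membrane and cytoskeleton genes 5 rose and 12 fell (5 and 12 adjusted over the list alone). The water channel gene AQP1 fell from 9.43 ± 0.188 to 2.83 ± 0.0198 RPKM, whereas TMCC2 rose 3.10-fold and SLC4A1, the band 3 anion exchanger, 1.33-fold. The heme, iron and membrane lists did not pass camera on log2 RPKM (adjusted p = 0.135, 0.117 and 0.231). On the reads the iron list passed, toward lower (adjusted p = 0.0447, adjusted p = 0.703 with an estimated correlation), and the heme and membrane lists did not (0.0983 and 0.0991). With no filter on low values the 3 lists passed on log2 RPKM too, toward lower (adjusted p = 0.0257, 0.0273 and 0.021, and adjusted p = 0.654, 0.608 and 0.608 with an estimated correlation). SLC4A1 did not pass edgeR with mapped-read scaling (adjusted p = 0.279), without vehicle replicate 1 (0.113) or without GC-1 replicate 1 (0.0940).

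Of 21 erythroid transcription factors 3 rose and 6 fell, and of 15 progenitor genes 5 rose and 4 fell (3 and 6, and 5 and 4, adjusted over the list alone). LMO2, a bridging member of the GATA1 complex, fell from 10.4 ± 0.408 to 3.91 ± 0.0974 RPKM and the repressor gene GFI1B was 1.74-fold lower, while FOXO3, a factor of late erythroid maturation, rose 1.59-fold. The integrin gene ITGA4 fell from 12.6 ± 0.519 to 5.42 ± 0.223 RPKM, the stem cell factor receptor gene KIT was 2.02-fold lower and MYB 1.88-fold lower, while GATA2 rose 2.16-fold. On log2 RPKM camera gave adjusted p = 0.212 and 0.887 for these lists. On the reads the transcription factor list passed, toward lower (adjusted p = 0.0233, adjusted p = 0.703 with an estimated correlation), as it did on log2 RPKM with no filter on low values (0.0252, adjusted p = 0.608 with an estimated correlation), and the progenitor list did not (0.149).

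Of 30 cell cycle genes 11 fell and 2 rose (11 and 2 adjusted over the list alone). CDK6 was 1.90-fold lower. CCND1, cyclin D1, rose 2.65-fold and did not pass glmTreat at the bound set by the luminal and long neuronal genes. The median was -0.13 relative to all genes (camera adjusted p = 0.0228, and 0.0296 on the reads, adjusted p = 0.574 with an estimated correlation). The call was lost without vehicle replicate 1 (adjusted p = 0.0698) or GC-1 replicate 2 (0.084), and the median lay at the 2.84th percentile of matched random lists in run 66 and the 32.2nd in run 80. Of 27 genes of organelle clearance and enucleation 11 rose and 5 fell (12 and 5 adjusted over the list alone). The autophagy kinase gene ULK1 rose 2.53-fold, the autophagy receptor gene SQSTM1 1.81-fold and the nuclear exporter gene XPO7 1.79-fold, while MYL4, a myosin light chain gene, was 2.08-fold lower. The median was 0.28 above that of all genes, beside 1.32 for the luminal breast genes, and its own value turned to -0.07 relative to mapped reads. The luminal breast genes lay at the 100th percentile of matched random lists in both runs, which tests nothing for a list written after the data had been seen. The organelle clearance list lay at the 99.8th percentile in run 66 and the 99.7th in run 80. Camera's adjusted p was 0.0307 (adjusted p = 0.574 with an estimated correlation) and the call was lost on the reads (0.327), with mapped-read scaling (0.0935), on the deposited FPKM tables (0.0822), with no filter on low values (0.128) and without GC-1 replicate 1 (0.168) or vehicle replicate 2 (0.107).

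Of 18 immediate early genes 7 rose and 0 fell, of 16 interferon response genes 6 and 0, of 18 cytokine feedback genes 8 and 2, and of 14 heat shock genes 6 and 1 (8 and 0, 7 and 0, 9 and 2, and 7 and 1 adjusted over the list alone). IRF1, an interferon-induced transcription factor gene, rose 2.43-fold, the survival gene BCL2L1 1.52-fold and HSPA1B, a heat shock gene with the near-identical copy HSPA1A, 1.72-fold. These lists passed camera on log2 RPKM (adjusted p = 0.00137, 0.00247, 0.00174 and 0.0212, each adjusted p = 0.574 with an estimated correlation) and did not pass on the reads (adjusted p = 0.155, 0.0816, 0.0521 and 0.134), and the heat shock list lost its call without GC-1 replicate 1 (0.102). Their medians lay 0.50, 0.68, 0.50 and 0.34 above that of all genes, beside 1.32 for the luminal breast genes. In each run they lay at the 97.9th percentile of matched random lists or above. The luminal breast genes lay at the 100th, which tests nothing for a list written after the data had been seen. The heat shock median turned to just below 0 itself relative to mapped reads. Of 12 glucocorticoid response genes 5 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0869, 0.229 on the reads and 0.0364 on the deposited FPKM tables, there adjusted p = 0.807 with an estimated correlation). TXNIP, a regulator of glucose uptake, rose 2.11-fold and FKBP5 was 1.71-fold lower.

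**Figure D4:**
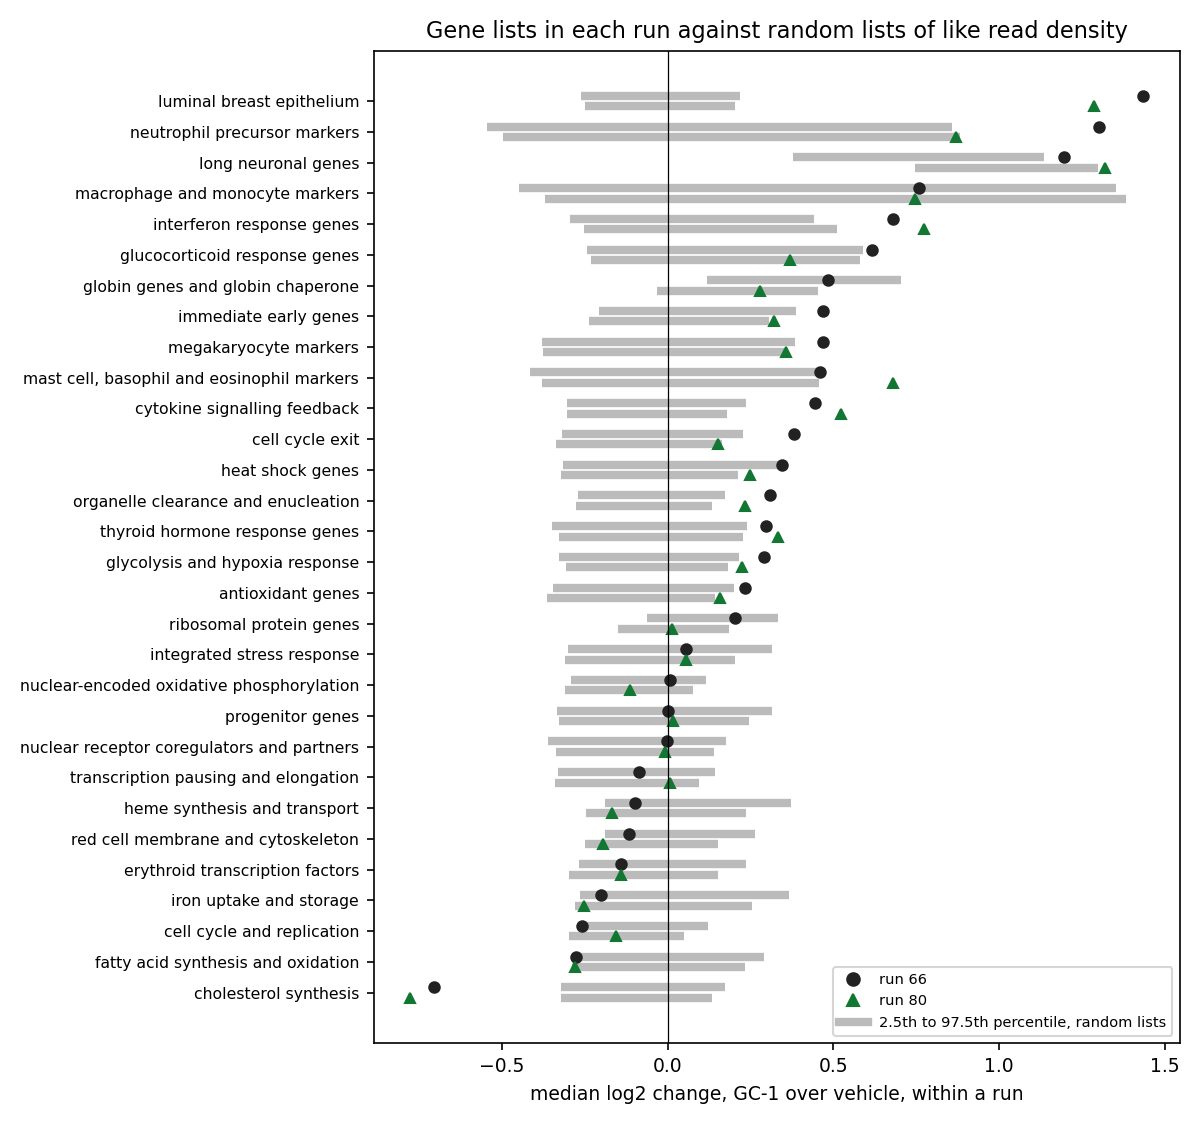
Median log2 change of each gene list (x axis) in run 66 (black circles) and run 80 (green triangles), relative to gene reads, with grey bars for the central 95% of 10000 random lists of matched read density. Cholesterol synthesis lies lowest at -0.70 and -0.78, and relative to mapped reads the limma medians of organelle clearance, heat shock, glycolysis, ribosomal protein and integrated stress response genes fall below 0.

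Some of the largest changes were in weakly read genes. FGF17, a fibroblast growth factor gene, had 0 reads in both vehicle libraries and 11 and 9 with GC-1, at least 13.8-fold higher against a floor of 3 reads over the vehicle group. LMOD1, a leiomodin gene of smooth muscle, had 1 and 8 reads with vehicle and 40 and 56 with GC-1, a ratio of 22.0 in pooled reads (95% counting interval 11.1 to 49.6). SLCO1C1, which encodes a thyroxine transporter, had 3 and 1 reads with vehicle and 10 and 20 with GC-1, a ratio of 15.5 (5.46 to 60.5). Without vehicle replicate 1 or 2, edgeR's adjusted p was 0.165 and 0.0968 for FGF17 and 0.10 and 0.107 for SLCO1C1. The 24 genes that limma's differences put first in both directions, none of them past its test, were microRNA and small nucleolar RNA genes with 0 to 5 reads per library.

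The changes within runs 66 and 80, which share no library, had a Spearman correlation of 0.53 and a Pearson correlation of 0.30 across 11026 genes, and of 0.58 and 0.58 across 8796 NM transcripts of at least 1000 bases. Genes are not independent replicates, so no p is given. Of the 8796 NM transcripts, called or not, 74.7% had the same direction in both runs. Of the 5411 genes called by edgeR, 5376 did, but these were chosen by a test on both runs, which makes a like direction nearly certain. The authors' deposited table lists 2854 genes higher and 2466 lower with GC-1 at an adjusted p under 0.05. The edgeR test here and the authors' deposited table share 4900 called genes, all with the same direction, and among the 14135 genes of the test 511 were called by the test here alone and 179 by the authors alone. Both rest on the same reads, and their log2 changes had a Pearson correlation of 0.9998, so the overlap is no independent check.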

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

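In this part the bound on the variance of the long neuronal genes was written before that value was computed, and all other tests, and the reading of that variance against replicates, were chosen after the values had been seen. Reads outside genes, which enter no comparison, made up 30.6% of mapped reads in GC-1 replicate 1 and 40.1% in GC-1 replicate 2, more than in the vehicle libraries (20.1% and 25.1%).

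Luminal breast and long neuronal genes, in lists written after the data had been seen, were higher in the GC-1 libraries. A uniform background is argued against, since the gain over the long neuronal genes varied at least 22.4 times as much as counting allows. Thinning the vehicle reads to the GC-1 depth hardly moves a median and so tests little (the luminal median was 1.42 and 1.25 after thinning, 1.44 and 1.29 before). Lower depth by itself is argued against for the luminal genes by their own reads. With GC-1 these were a median of 1.11 and 1.41 times those with vehicle, at depth ratios of 0.409 and 0.575. A candidate explanation is a like number of reads from cells of another type, or from another library, in each library: a first test set the luminal list above all 10000 matched random lists, which tests nothing for genes chosen for the pattern, and the test that replaced it, of 1 common factor over the long neuronal genes with a variance of at most 2 times counting, gave 6.12 times in run 66 and 2.66 times in run 80, a bound that was wrong because replicate libraries themselves differ by 2.38 to 3.19 times. Outside reads and an effect of GC-1 on these genes therefore cannot be told apart here. Run 66 lies above the replicate range of 2.38 to 3.19 and run 80 within it, but that range is over all genes. No such range was computed for the long neuronal genes, on which replicates differed unevenly: with vehicle DPP10 had 81 and 181 reads and EYS 536 and 478. The vehicle libraries also hold reads of their own on these genes, and gene counts do not show from which library a read came.

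Globin genes were higher in the GC-1 libraries. A candidate explanation is the limit of 3 reads per position, which holds back the deeper vehicle libraries more. The globin median lay at the 50.8th percentile in run 66 and the 70.8th in run 80 among 10000 random lists matched on the share of that limit reached, and genes at over 20% of the limit had medians of 0.59 and 0.27 on the log2 scale. That share is vehicle reads per base over a fixed limit, so this match nearly repeats the one on read density (48.6th and 68.8th percentiles). It cannot separate the limit from other effects that follow read density. Globin genes at a like share differed: HBD, at 10.7% of the limit with vehicle, had log2 changes of 1.00 and 0.65. HBG2, at 10.4%, had 0.48 and 0.28, and HBG1, at 10.2%, had 0.27 and 0.17. An effect of GC-1 on globin transcription stays open and was not separated from the limit.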

How the results depend on the processing

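The settings of the edgeR test, the deposited FPKM tables, the NM transcripts with no replicate block and camera on reads were chosen after seeing the data. The cause of the changes was not tested, apart from the fewer genes tested at a mean RPKM of at least 2. limma's count of 0 became 431 with no replicate block, 40 with mapped-read scaling, 40 without trend, 47 on the deposited FPKM tables, 836 for NM transcripts with no replicate block, and 0 to 58 with each library left out, where the lone library is assumed to vary like the others. It was 0 with the other filters, scalings and pseudocounts tried and for NM transcripts with the block. edgeR called 5411 and DESeq2 1804. edgeR's 5411 became 3350 with no replicate block, 1309 at a mean RPKM of at least 2, 6 with glmTreat, 1804 with DESeq2, and 1398 to 4688 with each library left out, and lay between 4485 and 6330 under the other settings. Camera's 15 lists became 9 at a mean RPKM of at least 2, 0 with an estimated correlation, 1 with fry (mast cell, basophil and eosinophil markers) and 7 on reads (higher for thyroid hormone response and globin, lower for iron, erythroid transcription factors, cell cycle, cholesterol and fatty acids), and 11 to 14 with each library left out. The Spearman correlation of 0.53 became 0.296 as Pearson's. For single genes in edgeR's test, 753 values under other settings kept their direction and side of the threshold, and 62, over 19 genes, lost the call. THRA, not called, changed sign: in limma its log2 difference was 0.040 with median centring, 0.11 in run 80 alone and -0.143 to 0.041 with each library left out, and in edgeR 0.070 with thinned vehicle reads and -0.169 to 0.047 with each library left out. The longest transcript was not run, since each table holds 1 transcript per gene. Depth limits genes with few reads, such as FGF17.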

Other observations

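Of 17 antioxidant genes 6 rose and 0 fell (5 and 0 adjusted over the list alone), with a median 0.37 above that of all genes (camera adjusted p = 0.0098, adjusted p = 0.574 with an estimated correlation), beside 1.32 for the luminal breast genes. Of 16 cell cycle exit genes 5 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.0483, adjusted p = 0.574 with an estimated correlation), with a median 0.36 above that of all genes. Relative to mapped reads the 2 lists' own medians were 0.016 and 0.006. Neither list passed camera on the reads (adjusted p = 0.213 and 0.593). Cell cycle exit also lost its camera call with no replicate block (0.0617), no filter (0.128), a mean RPKM of at least 2 (0.0819) or no trend (0.064). The same held with mapped-read (0.0935) or upper quartile scaling (0.0622), median centring (0.052), a pseudocount of 1 (0.0589) and the deposited FPKM tables (0.0693). It also held without vehicle replicate 1, GC-1 replicate 1 or vehicle replicate 2. The call stayed with TMM scaling, a pseudocount of 0.01 and NM transcripts of at least 1000 bases. Of 21 glycolysis and hypoxia genes 7 rose and 3 fell, of 15 integrated stress response genes 4 and 0, of 38 ribosomal protein genes 11 and 0, of 28 oxidative phosphorylation genes 2 and 1, and of 20 genes of pausing and elongation 2 and 3 (7 and 3, 4 and 0, 11 and 0, 0 and 0, and 2 and 3 adjusted over the list alone). Camera's adjusted p was 0.0634, 0.110, 0.140, 0.754 and 0.916 for these 5 lists on log2 RPKM, and on the reads 0.453 for the first 4 and 0.556 for the last, and the medians of the first 3 turned to below 0 relative to mapped reads. On log2 RPKM glycolysis passed without vehicle replicate 2 (0.0299, adjusted p = 0.510 with an estimated correlation). For NM transcripts of at least 1000 bases glycolysis (0.04) and the integrated stress response (0.0494) passed, each adjusted p = 0.523 with an estimated correlation. With no replicate block as well, these lists (0.0376 and 0.0284) and the ribosomal protein list (0.046) passed, adjusted p = 0.392, 0.271 and 0.562 with an estimated correlation.

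The tests of this part were chosen after the NETO2 values had been seen. NETO2 was higher in the GC-1 libraries, and its neighbour ITFG1, upstream on the same strand (chromosome 16, 47188300 to 47495185), fell by 0.26 on the log2 scale (edgeR adjusted p = 0.00253). Read-through from ITFG1 is argued against, since the RPKM of NETO2 was at least 10.3 times that of ITFG1 in each GC-1 library. A like number of outside reads in each library is argued against too, since NETO2 had 65 and 48 reads with vehicle and 1183 and 1309 with GC-1, ratios of 18.2 (95% counting interval 14.2 to 23.7) and 27.3 (20.4 to 37.2), where the highest ratio of 23 luminal genes with at least 20 vehicle reads was 1.64 in run 66 and 2.28 in run 80. Its rise also exceeded the 95th percentile of the luminal and long neuronal genes (edgeR's glmTreat, adjusted p = 3.44e-212), which sets no bound on a source richer in NETO2 and present in the GC-1 libraries alone. Such a source was not tested otherwise, and a response of NETO2 to GC-1 stays open as a hypothesis.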
